A study of Mus musculus with 9 samples.

How the data were processed

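Gene expression was measured by bulk RNA sequencing of whole mouse corneas in 9 libraries. The groups were wild type (WT, n = 3), untreated Aire knockout (KO, n = 2) and Aire knockout treated with PBS (KO + PBS, n = 4). A further group named in the series design, knockout corneas treated with Lacripep, was not analysed here. Per the labels' protocols, total RNA was purified with the RNAaqueous reagents and DNase and made into libraries with the NEBNext Ultra RNA kit. Per the submitters' processing notes, fastp, STAR and featureCounts were used with the mouse build mm10; their versions, the gene annotation, the handling of reads that map to several places and the strand setting are not given in the sources used here. The labels call the replicates biological and do not say whether each is 1 mouse or a pool, so p-values measure the spread between these samples.

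The deposited values are counts: the authors' table holds whole-number read counts per gene for each library, not normalized, for 34165 gene names, and every column of it was matched to a sample by name. Of these, 23 read as calendar dates and name no gene; they held 0.0318 to 0.140% of a library's counts and were left out of library sizes and tests. Gene positions and types were taken from GENCODE M21 (build GRCm38, the assembly of mm10), in which 31438 of the names matched 1 of 55450 genes, 986 of them through an older symbol. Library totals ranged from 22944576 to 104518572 counts. A count of 0 was taken to allow up to 3 counts per library, which is 0.029 CPM in the deepest library and 0.131 CPM in the shallowest. Such limits and the Wilson 95% intervals cover counting error only, since PCR copies are not independent molecules.

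Counts were compared with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes passed edgeR's filterByExpr, libraries were scaled with TMM factors, and 1 quasi-likelihood model with a mean per group was fitted to all 9 libraries with robust dispersion estimates. KO was compared with WT, KO + PBS with KO, and KO + PBS with WT, each over 18489 genes. Benjamini-Hochberg adjusted p under 0.05 counted as a call, and the words rose and fell are kept for calls. CPM values of genes are scaled by the TMM factors and given as mean ± SD; sums of CPM over a gene list are not scaled by them. Log2 fold changes are given ± SE. The SE is the fold change divided by the square root of the quasi-likelihood F. Folds against a group at 0 were computed only as bounds, against 3 counts per library.

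The groups, tests, gene lists, the rule for named genes and the alternatives, other than those named below as added, were fixed before the data were examined. Named genes are, per comparison and direction, the 10 with the largest log2 fold change among called genes with a mean of at least 2 CPM and no overlap between the groups' libraries, leaving out predicted genes, RIKEN names, "-ps" names and antigen receptor segments. Aire itself and, from each gene list, up to 4 members with the smallest adjusted p were added. The 42 gene lists cover cell types of the cornea and of the tissues next to it, leukocytes, and inflammatory and metabolic programmes; 41 had the 5 tested members needed for a set test. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with the correlation estimated from the data as an alternative, and with the rotation test fry. The list p-values are Benjamini-Hochberg adjusted over the lists of a comparison. Calls within a list are given over all genes and adjusted over the list alone.

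The steps were tested on simulated counts drawn from the real means and library sizes for 18489 genes. With 50 changed genes per fold, KO against WT recovered 8% of genes changed 2-fold, 66% of those changed 4-fold, 86% at 8-fold and 84% at 16-fold, and 5.4% of its calls were false. KO + PBS against KO recovered 18%, 88%, 86% and 92% with 9.6% false calls, and KO + PBS against WT 16%, 68%, 90% and 96% with 5.6%. In these simulations the groups compared had the same means apart from the changed genes. The real comparisons with KO + PBS called far more genes, so these rates need not hold for them.

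The alternatives were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, fits to only the groups compared, a test against a fold of 1.5 with glmTreat, the replicate number as a block, non-robust dispersion, leaving out X, Y and sex-linked genes, and leaving out each library in turn. Protein-coding genes with a count in all 9 libraries, and fits to the untreated groups without either KO library, were added after seeing the data. Overlaps between comparisons that share libraries were set beside the overlap of independent lists of the same size, and covariances and correlations of their fold changes beside 30 simulations without any effect. No library repeated another of its group, since the chi-square of each pair of count columns was 22.2 to 365 per degree of freedom, against 1 for sampling noise. Gene lengths, GC content and shared 31-base sequences came from the GENCODE M21 transcripts. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.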

Results

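Whole corneas were profiled by bulk RNA sequencing in 3 wild-type libraries, 2 libraries of untreated Aire knockout mice and 4 libraries of Aire knockout mice treated with PBS. Aire is the transcription factor that lets the thymus show tissue proteins to developing T cells. Mice without it lose self-tolerance, and the series design names the knockout as a model of dry eye disease. PBS is a salt solution that serves here as topical lubrication. The untreated libraries are titled 5 wk and the PBS libraries 24 hr, while the series design speaks of day 7 of treatment at 6 wk of age; the labels do not settle which holds. Totals were 38331620, 104518572 and 43256136 counts in WT replicates 1 to 3, 25356754 and 68534734 in KO, and 22944576 to 27116073 in KO + PBS.

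The 5 untreated libraries and the 4 PBS libraries held different kinds of counts. Processed pseudogenes, intronless copies of genes inserted elsewhere in the genome, took 17.6 to 22.1% of the counts in the untreated libraries and 0.289 to 0.361% in the PBS libraries. Genes of the mitochondrial genome had 0 counts in each untreated library, which allows at most 0.029 to 0.118 CPM. They took 0.797, 6.13 (Wilson 95% interval 6.12 to 6.14), 0.924 and 0.882% of the counts in KO + PBS replicates 1 to 4. The pseudogenes Rps19-ps1 and Rps19-ps2 had 22925 and 22924 counts in WT replicate 1 and 0 in each PBS library, whereas Raver1, which codes for an RNA-binding protein, had 0 in each untreated library and 1411 to 1683 in the PBS libraries. Spearman correlations across 15411 genes, which are not independent replicates, were 0.942 to 0.953 between WT and KO libraries, 0.583 to 0.628 between KO and KO + PBS, and at least 0.918 within each group. KO and WT therefore lie within 1 kind of library. The main fit to all 9 libraries still draws its filter and its estimate of spread from the PBS libraries too. The fit to the 5 untreated libraries alone does not. In both comparisons with KO + PBS the treatment and the kind of library cannot be told apart.

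**Figure D1:**
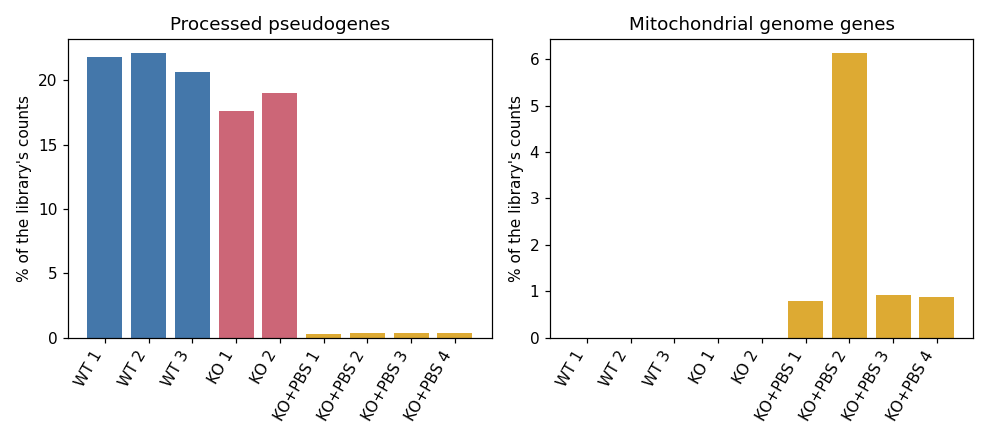
Percent of each library's counts on processed pseudogenes (left) and on genes of the mitochondrial genome (right), 1 bar per library, with WT in blue, KO in red and KO + PBS in yellow. Processed pseudogenes take 17.6 to 22.1% in the 5 untreated libraries and at most 0.361% in the 4 PBS libraries, and mitochondrial genes have counts only in the PBS libraries.

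Aire (chromosome 10, 78030022 to 78043610 in GRCm38) had 4, 16 and 3 counts in the WT libraries, 0 and 3 in KO, and 7, 9, 7 and 2 in KO + PBS. These counts are too few to check the genotype labels, and the deleted part of the gene is not given in the sources used here.

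The comparison of KO with WT asks what the knockout changes in the untreated cornea. Of 34 type I interferon response genes 9 rose, of 20 MHC class I presentation genes 9 rose, and of 31 genes of keratocytes, the matrix-making cells, and the corneal stroma 6 fell. Saa3, an acute-phase serum amyloid gene, rose from 0.303 ± 0.347 CPM (SD, n = 3) in WT to 513 ± 359 CPM (SD, n = 2) in KO, a log2 fold change of 10.81 ± 1.69 (SE). B2m, the shared light chain of MHC class I molecules, rose from 232 ± 54.7 to 2260 ± 468 CPM. Kera, which codes for keratocan, a proteoglycan needed for corneal transparency, fell from 480 ± 36.3 to 23.7 ± 0.883 CPM, a log2 fold change of -4.34 ± 0.69. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 178 genes rose and 130 fell among 18489 tested, and 3356 had an unadjusted p under 0.05. Fitted to the 5 untreated libraries alone, the same test called 2062 genes higher and 1619 lower, including 177 of the 178 and all 130. DESeq2 called 782 and 1088, and a test against a fold of 1.5 called 8 and 4. DESeq2 and a run with no filter (137 higher and 174 lower) thus called more genes lower than higher. Leaving out any 1 WT library left 0 calls in edgeR (2184 to 2392 genes at an unadjusted p under 0.05; DESeq2 387 to 452 higher and 506 to 535 lower). Leaving out KO replicate 1 left 28 higher and 19 lower, and KO replicate 2 left 39 and 11. Without KO + PBS replicate 2 the calls were 1247 and 1010, and without KO + PBS replicate 3 they were 73 and 72.

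**Figure D2:**
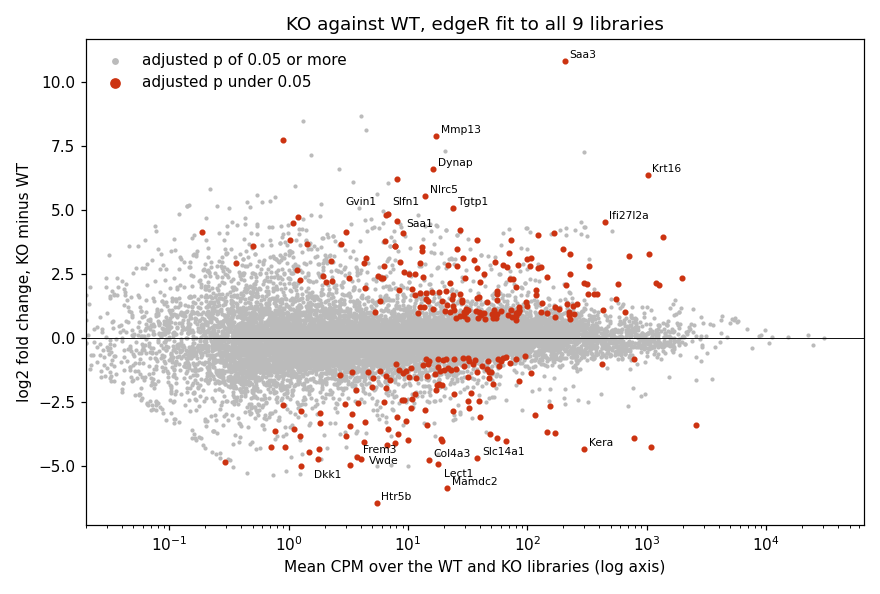
Log2 fold change of KO minus WT against the mean CPM over the 5 untreated libraries (log axis), 1 point per gene with a count in both groups, with genes called by edgeR in red and the named genes labelled. Saa3 lies highest at 10.81 and Htr5b lowest among the called genes at -6.43.

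Of the 10 called genes with the largest rise among those with a mean of at least 2 CPM and no overlap between libraries, Saa3 and Saa1 lie in 1 cluster of serum amyloid genes on chromosome 7 (46711998 to 46715700 and 46740497 to 46742980). Saa1 rose by a log2 fold change of 4.58 ± 0.82, from 0.802 ± 0.187 to 19.2 ± 14.1 CPM. Mmp13, a collagenase (chromosome 9, 7272514 to 7283331), rose by 7.88 ± 1.00 on the log2 scale, from 0.163 ± 0.0844 to 42.6 ± 27.5 CPM. Dynap rose by 6.60 ± 0.64, from 0.409 ± 0.138 to 39.8 ± 14.8 CPM. Krt16, a keratin of stressed and proliferating epithelium, rose by 6.37 ± 1.03, from 30.3 ± 6.86 CPM to 4520 CPM in KO replicate 1 and 475 CPM in KO replicate 2. The other 5 are interferon-induced: Nlrc5, the activator of MHC class I genes (log2 fold change 5.55 ± 0.71), the GTPase genes Tgtp1 (5.07 ± 1.01) and Gvin1 (4.85 ± 0.91), Slfn1 (4.79 ± 0.90) and Ifi27l2a (4.54 ± 0.70, from 44.6 ± 33.9 to 1040 ± 154 CPM). Tgtp1 has a near-identical neighbour, Tgtp2, and their reads can be counted for either gene.

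Among the 10 genes with the largest fall by the same rule, Prr32 had 668 counts in WT and 0 in both KO libraries, at least 41.4-fold lower against 3 counts per library. Htr5b, a serotonin receptor gene, fell from 9.07 ± 1.73 to 0.0824 ± 0.117 CPM (log2 fold change -6.43 ± 0.97), on 8 counts in KO. Mamdc2 fell from 35 ± 2.9 to 0.539 ± 0.491 CPM (-5.86 ± 0.92). Dkk1, a secreted inhibitor of Wnt signalling, fell from 5.38 ± 0.639 to 0.165 ± 0.0293 CPM (-4.97 ± 0.79). Lect1, which codes for chondromodulin, an inhibitor of blood vessel growth, fell from 29.1 ± 3.11 to 0.929 ± 0.229 CPM (-4.93 ± 0.45). Col4a3, a basement membrane collagen (chromosome 1, 82586921 to 82722059), fell from 24.4 ± 3.68 to 0.905 ± 0.144 CPM (-4.77 ± 0.76). Vwde (-4.73 ± 0.75), the urea transporter Slc14a1 (-4.69 ± 0.72), the extracellular matrix gene Frem3 (-4.65 ± 0.82) and Kera (chromosome 10, 97606879 to 97613692) complete the group.

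Of 34 tested type I interferon response genes, 9 rose over all genes and 32 adjusted over the list alone, with a median log2 fold change of 2.71. Oas2, an antiviral RNA sensor, rose from 22.5 ± 11.9 to 384 ± 77.7 CPM (adjusted p = 0.0231), and Irf7, the master regulator of the response, from 125 ± 38.5 to 553 ± 27.9 CPM (adjusted p = 0.0357). Of 28 interferon gamma response genes, 3 rose over all genes and 27 adjusted over the list alone, among them Igtp, from 11.7 ± 2.59 to 166 ± 66.7 CPM, and Ido1, which degrades tryptophan. Of 20 MHC class I presentation genes, 9 rose and 19 adjusted over the list alone, among them H2-K1 (167 ± 34.2 to 1530 ± 340 CPM) and H2-D1 (504 ± 30.2 to 2240 ± 411 CPM), whose sequences are so alike that their counts are uncertain. The camera test with a preset correlation of 0.01 called all 3 lists higher (adjusted p = 7.45e-33, 1.74e-23 and 1.2e-25); adjusted p = 0.417 with an estimated correlation for each. In the summed CPM of each list, both KO libraries lay above all 3 WT libraries. Type I interferon response genes summed to 815 to 1495 CPM in WT and to 7093 and 5083 CPM in KO.

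T cell transcripts were few in these corneas. Of 28 T cell genes, 0 passed over all genes in edgeR and 16 rose adjusted over the list alone, and the 5 untreated libraries alone gave 23. Their sum was 5.72 to 7.01 CPM in WT and 67.0 and 31.9 CPM in KO, and Cd3e had 0.0866 ± 0.0578 CPM in WT and 2.01 ± 0.545 CPM in KO (adjusted p = 0.0966). None of 8 cytotoxic cell genes (5 adjusted over the list alone), 15 B cell genes (0), 10 MHC class II genes (0) and 33 monocyte and macrophage genes (0) passed over all genes. The 5 untreated libraries alone gave 5 of 6 cytotoxic cell, 6 of 13 B cell and 9 of 10 MHC class II genes higher, and 8 of 33 monocyte and macrophage genes higher and 3 lower. Of 19 dendritic cell genes 1 rose, Fscn1, also adjusted over the list alone. Of 23 neutrophil genes 3 rose (20 adjusted over the list alone): Slfn4 (log2 fold change 4.21 ± 0.71), Il1b (3.77 ± 0.72) and Irg1 (7.73 ± 1.64), which macrophages also make. Of 10 mast cell genes 1 fell, the protease gene Cpa3, from 5.25 ± 0.650 to 0.682 ± 0.324 CPM, also adjusted over the list alone. By the camera test the T cell (adjusted p = 3.11e-14), cytotoxic cell (0.00014), B cell (0.000738), dendritic cell (0.00545), MHC class II (0.000623) and neutrophil (2.81e-12) lists were higher and the mast cell list lower (0.0158); adjusted p = 0.417 to 0.666 with an estimated correlation. Without KO replicate 1 the dendritic cell list gave an adjusted p of 0.0571, and without KO replicate 2 the mast cell list 0.402.

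Of 20 cytokine genes 2 rose (7 higher and 1 lower adjusted over the list alone), Il1b and Tnfsf10, and of 29 chemokine genes 1, Ccl4 (4 adjusted over the list alone). Of 20 antimicrobial and alarmin genes 2 rose, Saa3 and Saa1 (4 adjusted over the list alone). Of 23 matrix protease genes 3 rose (7 higher and 1 lower adjusted over the list alone): Mmp13, Mmp14 (37.0 ± 6.06 to 70.2 ± 9.95 CPM) and Mmp12 (0.396 ± 0.102 to 7.04 ± 6.19 CPM). Of 21 immediate early genes 1 rose, Jun (2 adjusted over the list alone). The camera test called the lists higher (adjusted p = 3.78e-06 for cytokines, 0.00127 for chemokines, 0.00202 for antimicrobial genes, 0.00318 for matrix proteases and 0.000755 for immediate early genes); adjusted p = 0.417 to 0.666 with an estimated correlation, and 0.0539 for matrix proteases without KO + PBS replicate 2. None of 15 complement genes passed over all genes, and 1 adjusted over the list alone; the 5 untreated libraries alone gave 3 higher and 5 lower of 14.

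In the stroma list, 6 of 31 tested genes fell over all genes, and 15 fell and 2 rose adjusted over the list alone, with a median log2 fold change of -1.68. Beside Kera, the proteoglycan gene Dcn (decorin) fell from 1240 ± 97.7 to 82.6 ± 11.6 CPM, the keratan sulfate sulfotransferase gene Chst5 from 77.2 ± 4.89 to 5.72 ± 0.865 CPM, and the corneal crystallin gene Aldh1a1 from 232 ± 27.6 to 36.6 ± 16.6 CPM. The list summed to 16039, 14618 and 17196 CPM in WT and to 4804 and 5412 CPM in KO. Of 16 genes of the corneal endothelium, the inner cell layer that keeps the stroma dehydrated, 1 fell, Car3 (270 ± 21.5 to 20.5 ± 9.46 CPM), and 10 fell and 1 rose adjusted over the list alone; the median was -1.91. The camera test called both lists lower (adjusted p = 2e-11 and 6.67e-07); adjusted p = 0.462 and 0.417 with an estimated correlation. Among basement membrane genes, the laminin gene Lamb3 rose, and Col4a3 and Nid1 fell. Of 26 myofibroblast and scar genes 2 fell, Postn and Cthrc1 (3 lower and 1 higher adjusted over the list alone), and the camera call for a lower list (adjusted p = 0.0434) was lost with upper-quartile scaling (0.087), without WT replicate 1 (0.0748), without either KO library (0.129 and 0.318), and at adjusted p = 0.743 with an estimated correlation. None of 23 Schwann cell and nerve support genes passed, also adjusted over the list alone, with a median of 0.07. The 5 untreated libraries alone gave 3 higher and 3 lower of 20. Of 22 neurotrophic and axon guidance genes none passed over all genes, and 2 rose and 7 fell adjusted over the list alone, as many as over all genes in the 5 untreated libraries alone.

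Among epithelial genes the basal keratin Krt14 rose from 748 ± 127 to 3840 ± 2060 CPM (adjusted p = 0.0253), 1 of 21 corneal epithelium genes to do so (5 adjusted over the list alone). That list was higher by the camera test (adjusted p = 0.0152; adjusted p = 0.666 with an estimated correlation, and 0.273 without KO replicate 2). Krt12, the keratin of the corneal epithelium, had 30300 ± 2710 CPM in WT and 30400 ± 11200 CPM in KO. Of 29 cornified epithelium genes Krt16 rose (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.12e-05, and adjusted p = 0.417 with an estimated correlation). Of 14 limbal and progenitor genes 2 rose, the metal-binding gene Mt2 and the cytokine signalling inhibitor Socs3 (3 adjusted over the list alone). Of 15 mucin and transport genes Muc1 rose, a membrane mucin (1 higher and 2 lower adjusted over the list alone), with Aqp1, a water channel, at 601 ± 34.9 CPM in WT and 130 ± 27.7 CPM in KO (adjusted p = 0.0624). Of 20 oxidative stress genes Mt2 rose (2 higher and 3 lower adjusted over the list alone), and of 20 hypoxia and glycolysis genes Car9 fell, from 16.1 ± 0.789 to 1.03 ± 0.236 CPM. None of 32 proliferation genes and 44 ribosomal protein genes passed, also adjusted over the list alone; the 5 untreated libraries alone gave 0 and 2 (lower).

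None of the genes of blood vessel endothelium (17 tested), lymphatic endothelium (8), conjunctiva and goblet cells (11), iris and ciliary body (15), skeletal muscle (16) or the lacrimal and meibomian glands (11) passed, over all genes or adjusted over the list alone, and of 7 red blood cell genes 1 fell adjusted over the list alone. In the 5 untreated libraries alone, 3 blood vessel genes were higher and 1 lower, 1 gene was lower in each of the lymphatic, conjunctiva, gland, red blood cell and retina lists, and 2 lens genes were lower. Lens (18) and retina (17) genes had 0 calls by either adjustment in the fit to all 9 libraries, and camera placed both lists lower in KO (adjusted p = 0.00331 and 0.00014; adjusted p = 0.666 and 0.656 with an estimated correlation, and 0.0841 and 0.0571 without KO replicate 1). The retina list summed to 366, 42.5 and 151 CPM in WT replicates 1 to 3 and to 22.6 and 33.0 CPM in KO. The lens list summed to 837, 670 and 401 CPM in WT and to 222 and 262 CPM in KO. The WT libraries thus differed widely among themselves in retina genes. Gland transcripts differed between the KO libraries: the lacrimal and meibomian gland list summed to 228 CPM in KO replicate 1, 1042 CPM in KO replicate 2 and 27.7, 49.3 and 70.05 CPM in WT. Xist, the X inactivation transcript of female cells, was present in all 9 libraries, at 194 ± 49.4 CPM in WT, 230 ± 15.9 CPM in KO and 504 ± 290 CPM in KO + PBS, and no other sex-linked transcript of the list had enough counts to be tested.

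**Figure D3:**
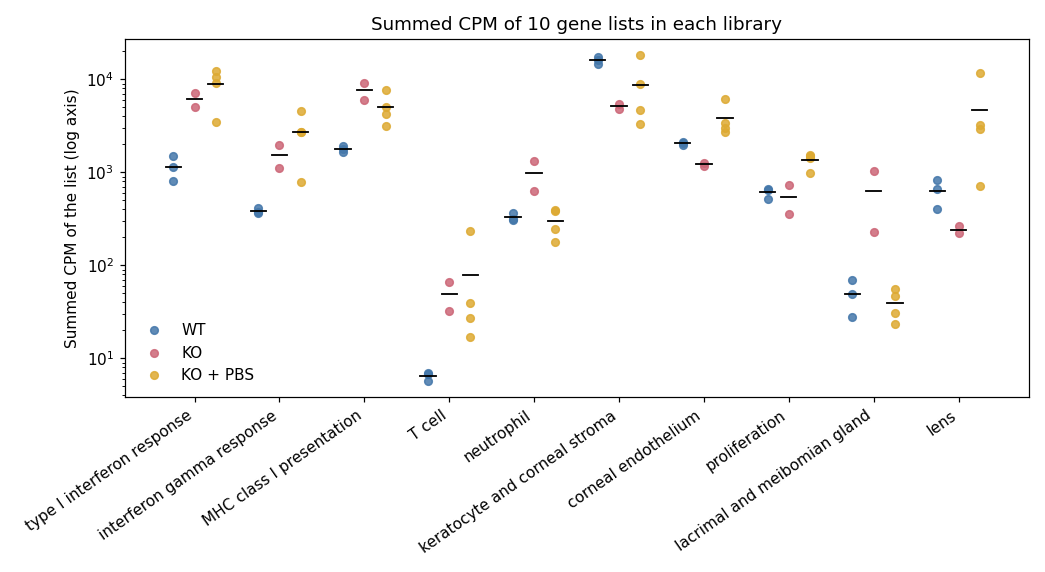
Summed CPM (log axis) of 10 gene lists in each library, with WT in blue, KO in red and KO + PBS in yellow; points are libraries and bars are group means. Stroma genes sum to 14618 to 17196 CPM in WT and to 4804 and 5412 CPM in KO, and the gland list reaches 1042 CPM in KO replicate 2.

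The comparison of KO + PBS with KO asks what topical PBS changes in the knockout cornea, across 2 sets of libraries whose counts differ in kind. Of 16 corneal endothelium genes 11 rose and of 23 basement membrane genes 7: Col4a3 from 0.905 ± 0.144 CPM (SD, n = 2) to 179 ± 120 CPM (SD, n = 4), a log2 fold change of 7.65 ± 0.85 (SE), and the sodium pump subunit gene Atp1b1 from 1.99 ± 0.308 to 149 ± 106 CPM (6.24 ± 0.70). Saa3 fell by 8.93 ± 1.36 on the log2 scale, to 1.06 ± 1.71 CPM, and Krt16 by 5.34 ± 0.88, to 61.8 ± 42.9 CPM. Kera rose from 23.7 ± 0.883 to 111 ± 71.7 CPM (adjusted p = 0.0123). In edgeR, 4370 genes rose and 5500 fell, and with upper-quartile scaling 5272 rose and 4881 fell. Among the protein-coding genes with a count in every library, 3289 rose and 3394 fell. Upper-quartile scaling moved the median log2 fold change of all genes from -0.02 to 0.17.

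The genes with the largest changes had 0 counts in each library of 1 group. The mitochondrial genes mt-Co1 (5820 ± 6260 CPM), mt-Cytb (2820 ± 3050 CPM), mt-Nd1, mt-Nd5, mt-Nd4, mt-Nd2 and mt-Nd6 led the higher genes, followed by Raver1 (49.8 ± 7.56 CPM), Chtf8 (48.1 ± 6.36 CPM) and Nupl1 (35.8 ± 14.2 CPM), all at 0 in both KO libraries. All 10 genes with the largest fall had 0 counts in each PBS library. They are the odorant-binding protein genes Obp1a and Obp1b, the secretoglobin genes Scgb2b2, Scgb1b7, Scgb1b2, Scgb1b11, Scgb1b29, Scgb2b20 and Scgb2b7, and RP23-435I22.2 (494 ± 19.6 CPM in KO). Obp1a had 25.1 CPM in KO replicate 1, 1410 CPM in KO replicate 2 and 45.6 ± 22.8 CPM in WT. Both families are made of near-identical copies, and Scgb1b2 and Scgb2b2 overlap on opposite strands (chromosome 7, 31290519 to 31291821 and 31290508 to 31304977), so the counts of single members are uncertain.

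Of 16 corneal endothelium genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), including Cdh2 and Col8a1, an endothelial collagen (13.3 ± 1.74 to 125 ± 69.2 CPM). Of 31 stroma genes 8 rose and 6 fell (8 and 5 adjusted over the list alone); Chst5 rose from 5.72 ± 0.865 to 52.3 ± 30 CPM and Ogn, a stromal proteoglycan gene, from 10.6 ± 0.0975 to 57.5 ± 30.5 CPM. The stroma list summed to 3343, 18178, 4673 and 8909 CPM in KO + PBS replicates 1 to 4. Of 23 basement membrane genes 7 rose and 3 fell (6 and 3 adjusted over the list alone), among them Col4a5 and Col4a4 (1.93 ± 0.114 to 148 ± 98.7 CPM). Of 32 proliferation genes 13 rose and 1 fell (12 and 1 adjusted over the list alone), with Prc1, which bundles the microtubules of the dividing cell, at 2.13 ± 1.67 CPM in KO and 33.3 ± 6.30 CPM in KO + PBS. Lens genes rose in 16 of 18 cases (17 adjusted over the list alone) and retina genes in 13 of 17 (16 adjusted over the list alone). The lens list summed to 3212, 11655, 712 and 2924 CPM in KO + PBS replicates 1 to 4, and the retina list to 55.1, 639, 1874 and 1459 CPM. All 12 mitochondrial genes were called higher, also adjusted over the list alone, and 41 of 44 ribosomal protein genes fell (42 adjusted over the list alone). Rpl24 had 359 ± 141 CPM in KO and 0.394 ± 0.108 CPM in KO + PBS, and ribosomal protein genes have many processed pseudogenes. The camera test called the endothelium (adjusted p = 0.0122), proliferation (0.0194), lens (0.00448), retina (0.0194) and mitochondrial (8.42e-06) lists higher and the ribosomal list lower (4.3e-06); adjusted p = 0.976 with an estimated correlation for each. It lost the proliferation list without KO replicate 2 (0.163) or KO + PBS replicate 1 (0.0762), the lens list without KO + PBS replicate 2 (0.0522) and the retina list without KO replicate 1 (0.0628) or KO + PBS replicate 2 (0.167).

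Of 29 cornified epithelium genes 18 fell and 0 rose in edgeR, also adjusted over the list alone, of 20 antimicrobial genes 12 fell, and of 23 neutrophil genes 12 fell, both also adjusted over the list alone. Pglyrp1, a peptidoglycan-binding protein gene, fell from 3610 ± 1040 to 380 ± 197 CPM, S100a8, a subunit of calprotectin, from 11.7 ± 8.14 to 0.257 ± 0.249 CPM, and Mmp13 from 42.6 ± 27.5 to 2.09 ± 2.00 CPM. Of 20 MHC class I genes 14 fell (14 adjusted over the list alone, with 1 higher), of 20 cytokine genes 7 fell (6 adjusted over the list alone), among them Il1b, and of 20 oxidative stress genes 13 fell and 2 rose, also adjusted over the list alone. Interferon genes moved both ways: of 34 type I genes 1 rose, Ifit2 (6.11 ± 1.88 to 38.3 ± 11.7 CPM), and 3 fell (1 and 2 adjusted over the list alone), and of 28 interferon gamma genes 3 rose and 3 fell (1 and 1 adjusted over the list alone). Of 28 T cell genes 1 rose, Tigit (0 adjusted over the list alone). Of 21 corneal epithelium genes 3 rose and 9 fell (4 and 10 adjusted over the list alone): Pax6, the master regulator of eye development, rose from 123 ± 13 to 468 ± 125 CPM, and Krt12 fell from 30400 ± 11200 to 4940 ± 948 CPM. The camera test called none of these lists (adjusted p = 0.0702 to 0.806). In the fit to KO and KO + PBS alone it called the antimicrobial (adjusted p = 0.00595), neutrophil (0.00822), MHC class I (0.0272) and cornified epithelium (0.0288) lists lower; adjusted p = 0.997 with an estimated correlation for each. In the fit to all 9 libraries the rotation test fry called the oxidative stress (adjusted p = 0.000489), antimicrobial (0.0031) and cornified epithelium (0.0037) lists. It also called the neutrophil (0.00519), MHC class I (0.0374) and cytokine (0.0465) lists, and the lacrimal and meibomian gland list (0.0037). Fry did not call the corneal epithelium, T cell, type I interferon and interferon gamma lists (0.154 to 0.997). No group lies in both sets of libraries, so none of these differences can be split into treatment and kind of library.

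The comparison of KO + PBS with WT asks how far the treated knockout cornea lies from the wild-type cornea, again across both kinds of library. Interferon-induced genes were higher in KO + PBS: Nlrc5 rose from 0.728 ± 0.376 CPM (SD, n = 3) to 46.5 ± 27.2 CPM (SD, n = 4), a log2 fold change of 6.02 ± 0.69 (SE), and the GTPase gene Gbp9 from 1.38 ± 0.662 to 52.9 ± 31.8 CPM (5.25 ± 0.78). Kera fell by 2.12 ± 0.47 on the log2 scale (adjusted p = 0.0044), and the stromal collagen gene Col6a1 fell from 1400 ± 34.4 to 235 ± 161 CPM. In edgeR 5002 genes rose and 5553 fell, and with upper-quartile scaling 5662 rose and 5083 fell. Among the protein-coding genes with a count in every library these numbers were 3620 and 3506. Upper-quartile scaling moved the median log2 fold change of all genes from 0.05 to 0.17.

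Of 34 type I interferon genes 31 rose (32 adjusted over the list alone), among them Oas2 (22.5 ± 11.9 to 324 ± 145 CPM) and Herc6 (6.32 ± 0.774 to 102 ± 58.2 CPM), and of 28 interferon gamma genes 22 rose (23 adjusted over the list alone). KO + PBS replicate 2 was the lowest of its group in both lists, at 3461 CPM against 9073 to 12228 CPM for type I genes and at 784 CPM against 2714 to 4514 CPM for interferon gamma genes. Of 28 T cell genes 18 rose, also adjusted over the list alone, with sums of 17.1, 39.5, 27.4 and 234 CPM in KO + PBS replicates 1 to 4. Of 31 stroma genes 18 fell and 2 rose (19 and 2 adjusted over the list alone); Bgn, a stromal proteoglycan gene, fell from 1350 ± 55.6 to 247 ± 161 CPM. Of 20 MHC class I genes 10 rose and 3 fell (11 and 3 adjusted over the list alone), with B2m at 1030 ± 480 CPM. Of 20 antimicrobial genes 9 fell, also adjusted over the list alone, while Saa3 (1.06 ± 1.71 CPM, adjusted p = 0.255) and Krt16 (61.8 ± 42.9 CPM, adjusted p = 0.278) did not pass. Of 23 basement membrane genes 7 rose and 2 fell (6 and 0 adjusted over the list alone), with Col4a3 at a log2 fold change of 2.88 ± 0.54. Of 32 proliferation genes 15 rose and 3 fell (15 and 4 adjusted over the list alone), of 18 lens genes 14 rose (17 adjusted over the list alone), all 12 mitochondrial genes were called higher, also adjusted over the list alone, and 43 of 44 ribosomal protein genes fell, also adjusted over the list alone.

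The camera test called the type I interferon (adjusted p = 9.92e-07), interferon gamma (9.22e-05), T cell (0.00849), proliferation (0.0275), lens (0.0174) and mitochondrial (1.26e-06) lists higher and the ribosomal list lower (4.87e-09); adjusted p = 0.962 with an estimated correlation for each. It lost the T cell list without KO + PBS replicate 2 (0.0859), the proliferation list without WT replicate 1 (0.0706), KO + PBS replicate 1 (0.101) or 4 (0.0756), and the lens list without KO + PBS replicate 1 (0.0845) or 2 (0.196). Of lists that camera did not call, the rotation test fry called the stroma (adjusted p = 0.0487) and antimicrobial (0.014) lists. It also called the oxidative stress (0.000309), limbal and progenitor (0.00633), red blood cell (0.031) and lacrimal and meibomian gland (0.031) lists. The conjunctiva and goblet cell (0.0434) and cornified epithelium (0.0487) lists were called by fry as well. Fry did not call the MHC class I (0.349) and basement membrane (0.144) lists. Of the lists that camera called, fry did not call the T cell (0.161), proliferation (0.155) and lens (0.13) lists. Beside the mitochondrial genes, Raver1, Nupl1 and Pnp (29.8 ± 7.03 CPM) were at 0 in each WT library. The lower genes RP23-435I22.2, AC122223.2, RP23-58N8.1, RP24-292B21.3, the ferritin pseudogene Ftl2, Il11ra2, RP23-389M9.5, RP23-239F1.2 and Olfr77 had 95.5 to 657 CPM in WT and 0 counts in KO + PBS, and Rps12l2 had 693 ± 36.9 CPM in WT and 2 counts in all 4 PBS libraries.

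Of the 178 genes that rose in KO, 126 were called lower in KO + PBS than in KO and 7 higher. Of the 130 genes that fell in KO, 93 were called higher in KO + PBS and 16 lower. Saa3, Saa1, Mmp13, Dynap, Krt16 and Gvin1 fell in KO + PBS, and Nlrc5 (log2 fold change 0.47 ± 0.59, adjusted p = 0.529), Tgtp1 (-0.40 ± 0.84, 0.715), Slfn1 (-0.15 ± 0.76, 0.882) and Ifi27l2a (-0.88 ± 0.61, 0.247) did not pass. Htr5b, Mamdc2, Dkk1, Lect1, Col4a3, Vwde, Slc14a1, Frem3 and Kera all rose in KO + PBS, Dkk1 to 7.04 ± 5.21 CPM and Slc14a1 to 81.2 ± 60.9 CPM. Independent lists of these sizes would share 53 and 30.7 genes. Both comparisons use the KO libraries, and 2 libraries cannot be split so that each part keeps 2; part of the excess may come from the shared libraries. The covariance of the log2 fold changes was -0.658 (-0.234 in 30 simulations with no effect), and their Pearson r was -0.167 (simulated -0.659). The simulations held no difference between kinds of library, while the observed KO + PBS minus KO fold changes had an SD of 3.76. Neither the observed covariance nor the observed r can therefore be set against its simulated value. With KO replicate 1 used to call and KO replicate 2 to measure, 34 of 38 raised genes (89.5%) and 6 of 11 lowered genes (54.5%) moved toward WT in KO + PBS. In these 38 the median log2 difference was 1.71 for KO minus WT and -1.9 for KO + PBS minus KO. With the roles exchanged, 20 of 28 raised genes lay above WT in KO replicate 1 (median log2 difference 0.11). KO + PBS lay lower than KO replicate 1 in 27 of these 28 (96.4%). The median of KO + PBS minus KO was -5.75, far more than that rise, so they show no return to WT. Of 19 lowered genes 12 (63.2%) moved toward WT. Called from the 3 WT libraries and KO replicate 1 or 2, 63.7% and 75.3% of raised genes and 44.1% and 55.7% of lowered genes did so. Of all genes, 53.2% lay lower in KO + PBS than in KO replicate 2, and 52.6% lower than in KO replicate 1. These shares are a baseline for raised genes only, since lowered genes move toward WT by rising. Leaving out any 1 WT library took both counts to 0. Without KO replicate 1 they were 26 and 12, and without KO replicate 2 they were 35 and 7. Leaving out KO + PBS replicate 2 gave 660 and 492, and KO + PBS replicate 3 gave 49 and 61.

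In both KO and KO + PBS, 142 genes were called in the same direction against WT, 85 higher and 57 lower, and 26 were higher in KO but lower in KO + PBS and 28 the reverse. Nlrc5, Tgtp1, Slfn1 and Ifi27l2a were higher in both, and Kera, Prr32, Htr5b and Lect1 lower in both. Independent lists would share 48.2 and 39 genes. The shared WT libraries cannot be split so that each part keeps 2, so part of the excess may come from them. The covariance was 0.439 (simulated 0.137) and Pearson r 0.112 (simulated 0.46), with the same limit on both. Leaving out any 1 WT library took the count to 0, KO replicate 1 left 14, KO replicate 2 left 22, KO + PBS replicate 2 gave 1211 and KO + PBS replicate 3 gave 63.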

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

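Library values of KO + PBS were examined for a library far from the 3 others, by a test planned before the values were seen (Dixon's ratio); the TMM-scaled CPM of single genes used for it was chosen after a first look at unscaled values. Of 96 values, 21 had a library past the bound: 1 in KO + PBS replicate 1, 14 in replicate 2, 2 in replicate 3 and 4 in replicate 4. Chance alone places about 1 in 20 values past it, and the values are not independent, since the mitochondrial genes were seen 9 times (single genes, their sum and their percent). The WT and KO groups, of 3 and 2 libraries, were not tested in this way.

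KO + PBS replicate 2 had 6.13% of its counts on mitochondrial genes, against 0.797 to 0.924% in the 3 others, and a summed mitochondrial CPM of 61300 against 7970 to 9240. The single genes were mt-Co1 at 15200 CPM (others 2600 to 2730), mt-Cytb at 7390 (1260 to 1320), mt-Nd1 at 5980 (966 to 1070), mt-Nd5 at 3950 (502 to 731), mt-Nd4 at 3390 (533 to 598), mt-Nd2 at 2800 (443 to 516) and mt-Nd6 at 1020 (158 to 182). The same library was high in genes of the iris, ciliary body and pigment cells (6280 CPM, others 183 to 718), in neurotrophic and axon guidance factors (1490, others 793 to 854) and in Prr32 (0.795, others 0.0839 to 0.164). It was low in cornified epithelium genes (7160, others 14300 to 15000) and in B cell and plasma cell genes (1350, others 2160 to 2280).

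KO + PBS replicate 4 was high in T cell genes (234 CPM, others 17.1 to 39.4), cytotoxic and NK cell genes (63.6, others 3.09 to 9.56), monocyte and macrophage genes (1740, others 581 to 728) and Saa3 (3.6, others 0 to 0.454). KO + PBS replicate 3 had 27.1 M counts (others 22.9 to 23) and 361 CPM of skeletal muscle genes (others 55.6 to 99.5). KO + PBS replicate 1 had 61.1 CPM of Raver1 (others 44.9 to 47.1). No explanation was tested for these libraries.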

How the results depend on the processing

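The protein-coding genes with a count in every library, and the fits to WT and KO without a KO library, were chosen after the results were seen; the other alternatives were planned. No named gene and no called list changed direction under any alternative run. The balance of calls did: more genes were lower than higher between KO and WT with DESeq2, no filter (137 and 174), the replicate number as a block and the fit without KO replicate 1 to WT and KO. More were higher than lower in KO + PBS with upper-quartile scaling against KO (5272 and 4881) and against WT (5662 and 5083), and with the protein-coding genes against WT (3620 and 3506).

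Between KO and WT the number of calls moved most. Against 178 higher and 130 lower, DESeq2 gave 782 and 1088, a fit to only the groups compared 2062 and 1619, and a test against a fold of 1.5 gave 8 and 4. Fits to WT and KO without KO replicate 1 gave 3051 and 3239, and without KO replicate 2 gave 2783 and 2609; 167 of the 178 and all 130 were shared in either case. Leaving out 1 library in the fit to all 9 gave 0 to 1247 higher and 0 to 1010 lower, with 0 without any WT library in edgeR (2184 to 2392 genes at an unadjusted p under 0.05). Without a KO library the lone KO sample is assumed to vary like the other groups. The variation between replicate libraries (biological coefficient of variation) was 37% in the fit to 9 libraries and 22% in the fit to WT and KO, which goes with the larger number of calls in the latter. The cause of the other moves was not tested. RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, non-robust dispersion, leaving out X, Y and sex-linked genes, and the protein-coding genes gave 137 to 245 higher and 125 to 187 lower.

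KO + PBS against KO and against WT stayed within 1.5 times its number of calls in all alternatives but 1. With the protein-coding genes, 3394 and 3506 genes were lower in place of 5500 and 5553, and 3289 and 3620 higher in place of 4370 and 5002. That run tested 14247 genes in place of 18489, leaving out pseudogenes, other genes that are not protein-coding, and genes at 0 in any library. What part of the loss goes with each was not tested. Leaving out 1 library gave 2947 to 5167 higher and 4278 to 6572 lower against KO, and 3798 to 5717 and 4638 to 6645 against WT.

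The overlaps moved with the calls between KO and WT. Genes raised in KO and lower in KO + PBS numbered 452 with DESeq2, 582 with only the groups compared, 5 with a fold of 1.5 and 0 to 660 leaving out 1 library. Genes lowered in KO and higher in KO + PBS numbered 532, 484, 3 and 0 to 492, and genes called in the same direction against WT numbered 896, 1383, 8 and 0 to 1211.

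Whether the replicate numbers pair the samples is not known. Deviations from the group mean correlated between libraries of the same number in different groups at -0.343 to 0.132, and of different numbers at -0.196 to 0.296. In groups this small the deviations within a group cancel, so these correlations cannot exclude pairing. With the replicate number as a block, 2 genes were higher and 3 lower between KO and WT, and the 3 overlaps were 1, 3 and 3 genes.

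Of the 20 named genes between KO and WT, 20 kept their call with only the groups compared, 4 with a fold of 1.5, 2 without KO replicate 1, 5 without KO replicate 2, 16 without KO + PBS replicate 3 and 0 without any WT library. The named genes of both comparisons with KO + PBS kept their calls in every alternative that tested them. Almost all of them had 0 counts in every library of 1 group, so the kind of library alone can keep these calls. The run on protein-coding genes with a count in every library tested none of them.

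Of 22 lists called between KO and WT, 0 kept the call with an estimated correlation or with fry, and of 6 and 7 lists in the comparisons with KO + PBS, 0 with an estimated correlation and 3 and 4 with fry. Over the alternatives the adjusted p of the myofibroblast list ran from 0.00205 to 0.743, corneal epithelium 0.000425 to 0.666, matrix proteases 2.39e-07 to 0.601, dendritic cells 0.000161 to 0.666, mast cells 1.67e-11 to 0.479, lens 1.18e-08 to 0.666 and retina 2.65e-07 to 0.656. In KO + PBS against KO it ran from 3.77e-05 (proliferation), 1.21e-06 (lens) and 0.00205 (retina) to 0.976. Against WT it ran from 0.000598 (T cell), 0.0054 (proliferation) and 3.92e-05 (lens) to 0.962.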

Other observations

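The tests of stroma genes against Schwann cell genes, of scaling, of shared sequence and of 2 library sets were chosen after the result was seen; the tests of length and GC content, of chromosome position and of other splits were planned.

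The median log2 fold change between KO and WT was -1.68 for stroma genes and -1.91 for endothelium genes. If KO pieces held less stroma of every kind, Schwann cell genes, whose cells also lie in the stroma, would fall with it. Their median log2 fold change was 0.07 (23 genes, 3 of them also in other lists) with quartiles of -0.70 and 0.31, apart from that of the stroma list (permutation p = 0.00025), and 0.10 in the fit to WT and KO alone, with 3 genes higher and 3 lower. That p shuffles genes between the lists as if they were independent, while the estimated correlation between stroma genes was 0.624. It does not measure the spread between samples. The Schwann cell median goes against an even loss of stroma in these KO libraries only. The scalings moved the stroma median by at most -0.06, which argues against scaling as the cause. A lower number of keratocytes, lower expression per keratocyte and a difference in dissection that spares nerves may each remain, as may an effect of the knockout. None of these was tested. Among lists of neighbouring tissues, lens and retina genes had medians of -1.12 and -2.89, with no gene called. Conjunctiva, iris and ciliary body, gland and skeletal muscle genes had medians of 0.02, 0.26, 0.82 and 1.31.

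KO + PBS libraries lay apart from the untreated libraries. Reads that map to several places may add to this but are not the whole cause: among 5588 protein-coding genes that share no 31-base sequence with another gene, the interquartile range of log2 fold changes between KO + PBS and KO was 2.21 times that between KO and WT (1.69 against 0.768). A trend on transcript length and GC content removed 22.1% of the variance in these genes (Spearman rho 0.50 with length and -0.37 with GC), which lies between the bounds set beforehand (under 20% and over 50%) and leaves it open. The highest Spearman correlation between a KO and a KO + PBS library was 0.628. Mitochondrial genes had 0 counts in each untreated library and 183027 to 1405073 in the PBS libraries. Processed pseudogenes took 17.6 to 22.1% of the counts in the untreated libraries and at most 0.361% in the PBS libraries. For genes of these 2 kinds, the values argue against PBS, age or time as the whole cause. For the other genes, libraries made or counted as 2 sets and an effect of PBS, age or time cannot be told apart, since each group lies in 1 set only.

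Genes called between KO and WT may gather near Aire or near H2-K1 if the knockout carries a stretch of another strain. Within 20 Mb of Aire 8 of 374 tested genes were called, 1.28 times the share elsewhere (Fisher p = 0.416). The 8 include the stroma gene Kera (chromosome 10, 97606879 to 97613692), since only Aire itself was left out there. Within 20 Mb of H2-K1, leaving out antigen presentation and interferon genes, 13 of 582 were called, 1.45 times the share elsewhere (Fisher p = 0.175). Both ratios lie under the bound of 1.5 set beforehand, but the 95% intervals of the odds ratios (0.548 to 2.60 and 0.76 to 2.55) reach past 2, so they decide nothing. This reading of the intervals was set after the values were seen. With no gene left out, 24 of 887 tested genes on chromosome 17, which holds H2-K1, were called (2.71%). Fisher's test against the other chromosomes gave p = 0.0214, and 0.428 adjusted over the chromosomes.

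Of the 35 splits of the KO + PBS and WT libraries into 4 and 3, 1, the real one, called as many as 10555 genes. Each other split puts both kinds of library on 1 side or both, so the real split can stand out through the kind of library alone. The test therefore decides nothing about the groups. The highest other split called 7164 and set KO + PBS replicate 2 with the 3 WT libraries, which points to a structure of the samples beyond the 2 groups; the median of the others was 0 in edgeR. The split along the groups is also the split along the kind of library.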
